A study of Homo sapiens with 24 samples.

How the data were processed

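Gene expression was measured in lysates of H838, a human non-small cell lung cancer line, grown as a confluent monolayer that shared a transwell system either with HPAEC, primary human pulmonary artery endothelial cells, or with more H838 cells as the control. Per the labels, total RNA was isolated with a column kit (RNeasy Plus Mini), its quality was checked on a Bioanalyser, and biotinylated cRNA was made with a linear amplification kit (Ambion MessageAmp) and hybridized to Illumina HT-12 bead arrays. The array names in the labels place the 24 samples on 2 BeadChips of 12 arrays each. Chip 1 held 10 of the 12 HPAEC arrays together with the H838 arrays of 0 h (replicate 1) and 0.5 h, and chip 2 held the other H838 arrays and all replicate 2 arrays, so chip and co-culture nearly coincided.

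The deposited non-normalized table gives, per the file headers, a mean bead intensity for each probe and array on the linear scale, beside a detection p-value that compares the probe with negative control beads. A second deposited table, the series matrix, holds a normalized linear intensity made by the authors. Its column medians lay between 116.46 and 116.55, so the authors had brought the arrays to a nearly common distribution, and the software and settings they used are not given in the sources used here. The non-normalized table was the starting point and the series matrix served as an alternative. Of 47286 probes, 30080 were given 1 gene symbol by the supplied probe annotation, 8 had several and 17198 were not listed. Entrez identifiers of 30041 of the named probes were found in the supplied RefSeq gene table, and 0 symbols had to be changed. No coordinates are given, because the genome build behind the probe design is not named.

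Intensities were corrected for background with limma's normal-exponential model with control statistics inferred from the detection p-values (offset 16), quantile normalized over the 24 arrays and put on the log2 scale. Probes with a detection p-value under 0.01 on at least 2 arrays were kept (20054, of which 15292 were named), and the kept probe with the highest mean stood for its gene, which left 11494 genes. The other 4762 kept probes had no single gene name and were left out of the gene tests. The work used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Arrays have no read depth. The detection calls measure signal over background, and the number of arrays limits the precision.

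The grouping, the comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. All tests across genes used limma (linear model and moderated statistics, both sides) with the Benjamini-Hochberg adjustment and a threshold of 0.05. A model of 10 times, co-culture and chip over the 24 arrays (12 residual degrees of freedom) gave the co-culture effect (HPAEC minus H838), the time effect (moderated F over the 9 times after the scratch) and the mean change from 0 h in an early (0.5, 1 and 2 h), a middle (3, 4 and 5 h) and a late window (10, 15 and 24 h). A model with 1 mean per co-culture and window plus chip (15 residual degrees of freedom) tested whether the changes differed between co-cultures. A last model on the 8 arrays of the duplicated times, 0 and 24 h, had 3 residual degrees of freedom. Chip was a fixed term in each.

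Gene lists written from general knowledge covered ER stress and amino acid response, NF-kB and TNF targets, hypoxia and glycolysis, immediate early genes, p53 targets, TGF-beta targets, G1/S and replication, G2/M and mitosis, cholesterol synthesis, heat shock, NRF2 and redox, interferon-stimulated genes, mesenchymal and EMT genes, epithelial junctions and keratins, migration, integrins and proteases, ribosomal proteins, the TNF and SDF-1 axis, and markers of endothelial cells, of fibroblasts and smooth muscle, and of leukocytes. Each was tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the lists of a contrast. Over 7 contrasts the 20 lists made 140 tests. Lists that were added after the results were seen were tested with limma's fry and then, because few arrays stand behind each window, with a permutation test of the list median in which times were redrawn 999 times among the arrays of each co-culture (both sides).

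Named genes followed a rule. For the co-culture effect these were the 12 largest rises and 12 largest falls among genes past the threshold whose difference had the same sign at 9 or more of 10 times. For the time effect they were the 24 largest changes at any time with the same sign in both co-cultures, for each window the 6 largest in each direction, and for comparisons of duplicated arrays the 5 largest in each direction, or the 3 smallest p-values where none passed. For each list the 4 largest changes per contrast were added, and other members past the threshold are named in places to illustrate a list. Where a gene was detected on no array of 1 side, a lower bound of the fold was computed by setting that side to the lowest normalized value of any detected probe on each array, unless the value itself was higher.

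Each comparison was tested on simulated data made from the residual spread of these arrays, with 11494 genes of which 100 changed by 0.5 and 100 by 1 on the log2 scale. At these sizes the co-culture effect recovered 88 and 100, the early window 77 and 99, the middle window 82 and 98, the late window 77 and 98, and the time effect 57 and 96. The test of the difference between co-cultures recovered 18 and 72. Simulated genes held no changes between times of a window, so this recovery may be too high for real genes. With the duplicated arrays alone, the co-culture effect at 0 h recovered 0 and 60, at 24 h 0 and 26, and the change from 0 to 24 h 1 and 59 in the HPAEC co-culture and 0 and 43 in the H838 co-culture. Between 0 and 12 unchanged genes were called per run, and a list shifted by 0.2 was called at an adjusted p of 7.79e-29 with 0 of the 19 others. The simulated genes varied independently of each other, so this run does not test false list calls among correlated genes.

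Alternatives were no background correction, median scaling in place of quantile normalization, the series matrix values, no detection filter, detection on all 24 arrays, single probes, the chip left out or as a random block, a block for the replicate number, pairs of the same time and chip, each chip alone, scratched arrays only, other codings of time, and each array left out in turn.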

Results

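The series profiled H838 lung cancer cells at 10 times around a wound, unscratched (0 h) and then from 0.5 h to 24 h after repeated scratching of the monolayer. At each time the cells had shared their medium with HPAEC endothelial cells or with further H838 cells. There were 12 arrays per co-culture: 2 at 0 h, 2 at 24 h and 1 at each other time. Each array detected between 15488 and 17555 probes (32.75% to 37.13%) at median raw intensities of 108.81 to 129.96. The SD over genes of the log2 difference between duplicates lay between 0.216 and 0.263. The labels do not say whether duplicates came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical only. In the model of 10 times this spread comes mainly from times with 1 array per co-culture. There it holds departures from a co-culture difference that is equal at all times, so its SE and p-values rest on that assumption. In a principal component analysis the leading components held 17.9% and 15.3% of the variance. The series title names TNF, SDF-1 and tumour cell migration, so the comparisons ask how endothelial neighbours and wounding changed the transcripts of the tumour cells.

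Next to HPAEC, H838 cells held more transcripts of an amino acid and ER stress response. DDIT3 (CHOP), a transcription factor of that response, was higher by 0.79 ± 0.12 (log2 ± SE over 24 arrays, 1.73-fold). TRIB3, its pseudokinase target, was higher by 0.61 ± 0.13, the alanyl-tRNA synthetase AARS1 by 0.53 ± 0.10 and the asparagine synthetase ASNS by 0.41 ± 0.06. Of 25 measured genes of the ER stress and amino acid list 10 were higher, 0 lower and 15 not past the threshold (14 higher when adjusted over the list alone). The list's median was 0.21 (camera adjusted p = 2.93e-10, and adjusted p = 0.00641 with an estimated correlation). STC2, a secreted glycoprotein induced by ER stress, showed the largest rise with 0.92 ± 0.16 (1.89-fold), and PCK2, the mitochondrial PEP carboxykinase, rose by 0.50 ± 0.05. In the 4 pairs of arrays that shared time and chip the list's medians were 0.26, 0.25, 0.25 and 0.17.

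Targets of NF-kB and TNF were also higher beside HPAEC. CXCL1 and CXCL6, neutrophil-attracting chemokines, rose by 0.57 ± 0.11 and 0.31 ± 0.08. The chemokine gene CXCL8, detected on all 24 arrays, did not follow them at each time. Its difference, not adjusted for chip, lay below 0 at most times (0.188 at 0 h, -1.2 at 4 h, 0.122 at 24 h). On the list 2 of 23 measured members were higher with 0 lower (11 and 0 when adjusted over the list alone). The median was 0.19 (adjusted p = 1.22e-06, and adjusted p = 0.0113 with an estimated correlation), with same-chip pair medians of 0.19, 0.17, 0.28 and 0.11. Of the hypoxia and glycolysis list 4 of 26 were higher and 0 lower (11 and 3 adjusted over the list alone), among them ADM, which encodes the vasoactive peptide adrenomedullin (0.49 ± 0.06), ANKRD37 (0.51 ± 0.10) and the neuronal enolase ENO2 (0.33 ± 0.08). That list's median of 0.14 passed at the preset correlation (adjusted p = 0.0117) but not otherwise (adjusted p = 0.376 with an estimated correlation), and its same-chip pair medians were 0.20, 0.23, 0.11 and 0.058. Other rises were VGF, a secreted neuropeptide precursor (0.55 ± 0.06), and the AP-1 genes FOSL1 (0.36 ± 0.07) and JUN (0.28 ± 0.06). GDF15, a stress-induced cytokine, passed the threshold but was detected on 2 HPAEC arrays and 0 H838 arrays, so no fold is given.

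Lower beside HPAEC were CRYBA1, a lens crystallin gene (-0.70 ± 0.08), the DNA repair gene RAD51B (-0.69 ± 0.14), the transcription factor WT1 (-0.54 ± 0.09), RNF145, a ubiquitin ligase (-0.53 ± 0.08), and TMEM119, best known as a microglial marker (-0.52 ± 0.11). RAD51B and TMEM119 were detected on 8 of the 12 HPAEC arrays. The integrin subunit gene ITGAV (-0.31 ± 0.06), the desmosomal cadherin DSC2 (-0.28 ± 0.07), the interferon-responsive PARP9 (-0.49 ± 0.10) and the p53 targets TP53INP1 (-0.46 ± 0.08) and PLK2 (-0.38 ± 0.09) were lower as well. Of 16 measured genes of the migration, integrin and protease list ITGAV alone passed the threshold (2 higher and 1 lower when adjusted over the list alone; median 0.031, adjusted p = 0.573). MMP1, a collagenase on that list, gave 0.32 ± 0.11 (adjusted p = 0.124).

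Of the TNF and SDF-1 ligands and receptors, TNF, CXCR4 and ACKR3 were detected on 0 of 24 arrays, as were the cytokine genes IL6 and CCL2. The TNF receptor gene TNFRSF1A was detected on all 24 (-0.053 ± 0.068 for the co-culture effect) and TNFRSF1B on 18. There was signal for CXCL12, which encodes SDF-1, on 11 with 1 of its 3 probes and on 0 with the others. Of the TNF and SDF-1 axis 0 of 3 tested genes passed (median -0.053, adjusted p = 0.964). Endothelial markers were not higher beside HPAEC. VWF, CDH5 and KDR were detected on 0 arrays, and 28 of the 39 marker probes were detected on 0 HPAEC arrays. The median over these probes was -0.0024, and 0 of 6 tested endothelial marker genes passed (adjusted p = 0.908).

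The other lists did not pass for the co-culture effect. Among lists of the cell cycle and growth, the G1/S and replication list had 0 of 30 genes past the threshold (4 higher adjusted over the list alone; median 0.053, adjusted p = 0.068). The G2/M list had 1 of 33, the anaphase activator CDC20 at 0.25 ± 0.06 (median 0.021, adjusted p = 0.908). The immediate early list had 2 of 29, FOSL1 and JUN (3 adjusted over the list alone; median 0.039, adjusted p = 0.396). Cholesterol synthesis had 0 of 21 (1 higher and 2 lower over the list alone; median -0.086, adjusted p = 0.105) and NRF2 and redox 0 of 18 (median -0.092, adjusted p = 0.0733). Heat shock had 0 of 16 (median -0.018, and above 0 under median scaling; adjusted p = 0.908) and TGF-beta targets 0 of 14 (1 lower over the list alone; median 0.089, adjusted p = 0.105). The p53 list had 1 higher and 2 lower of 16 (3 and 3 over the list alone), with a positive median of 0.022 and a test direction that was down (adjusted p = 0.964). Epithelial junctions and keratins had 1 lower of 14 (3 over the list alone; median -0.064, adjusted p = 0.126). Interferon-stimulated genes had 1 lower of 17 (1 higher and 1 lower over the list alone; median -0.021, adjusted p = 0.964). Mesenchymal genes had 1 higher of 12, TGFBI, an extracellular matrix protein, at 0.27 ± 0.07 (2 higher and 1 lower over the list alone; adjusted p = 0.964). Fibroblast and smooth muscle markers had 0 of 10 (1 higher and 3 lower over the list alone; median -0.079, adjusted p = 0.396). Leukocyte markers had 0 of 5 (1 higher over the list alone), with a median of -0.12 and a test direction that was up (adjusted p = 0.964). The 16 ribosomal protein genes had a median of -0.00097, which was 0.024 under median scaling (adjusted p = 0.997).

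**Figure D1:**
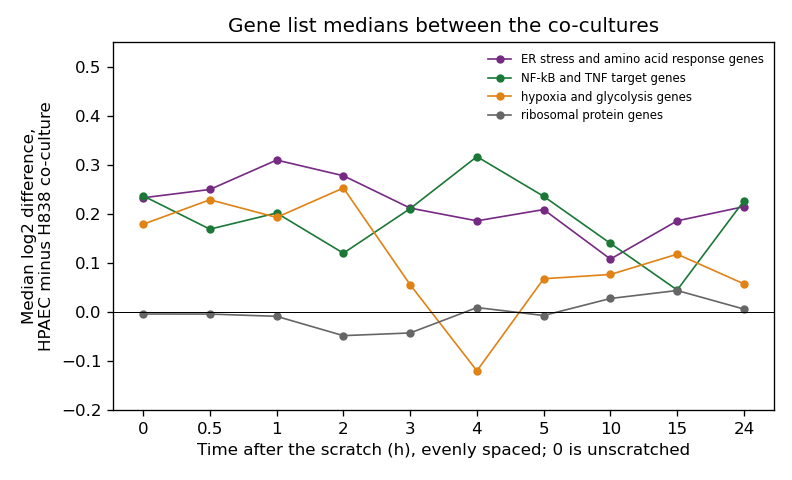
Median log2 difference between the HPAEC and the H838 co-culture (y axis) over the genes of 4 lists at each time (x axis, evenly spaced, 0 is unscratched); points are single array pairs, or means of duplicates at 0 and 24 h. The ER stress and amino acid list stayed above 0 at all 10 times (0.11 at 10 h, 0.31 at 1 h), and the hypoxia list went to -0.12 at 4 h.

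The co-culture test called 232 genes of 11494, 130 higher and 102 lower. Of these 190 kept their sign at 9 or more of the 10 times (114 higher, 76 lower). The pairs that shared time and chip carry much of this estimate (correlation 0.917 across genes), so the shared sign of all 232 there is not a separate test. Taken alone these pairs gave 0 genes past the adjusted threshold, with 231 of the 232 at an unadjusted p under 0.05. Over all genes 2 had a chip term past the threshold (767 at an unadjusted p under 0.05). The count was 5 under median scaling (4 higher, 1 lower), 10 without the H838 0 h replicate 1 array and 0 on either chip alone. It was 423 with detection required on all 24 arrays, 1723 with chip left out and 1949 with chip as a random block.

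After scratching 2629 genes differed from 0 h at some time, 1408 higher and 1221 lower at their largest change. No array was taken from unscratched cells after 0 h. The changes at all later times and windows therefore hold effects of time in culture and handling along with those of the scratch. FOS, the AP-1 transcription factor gene, was at least 14.3-fold higher at 1 h than on the unscratched arrays, where it was above background on 0 of 4. Its partner FOSB reached a log2 change of 4.14 ± 0.23 at 2 h and the U1 small nuclear RNA RNU1-3 3.96 ± 0.13 at 1 h. EGR1, a zinc finger immediate early gene, reached 3.11 ± 0.12 at 1 h and the signalling inhibitor SPRY4 1.74 ± 0.19 at 2 h. Among the falls were the glycolytic regulator PFKFB4 at 5 h (-1.87 ± 0.12), ANKRD37, a target of hypoxia-inducible factor, at 3 h (at least 3.63-fold lower) and TEF, a circadian output factor, at 10 h (at least 2.56-fold lower). ANKRD37 and TEF were above background on 0 of 2 arrays at these times. At single times, with 2 arrays each, 27 genes were higher and 1 lower at 0.5 h, 386 and 301 at 3 h, 630 and 574 at 10 h and 384 and 373 at 15 h. At 24 h, with 4 arrays, the calls were 669 and 646. Under median scaling 1347 genes passed the test, with 820 higher and 527 lower.

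**Figure D2:**
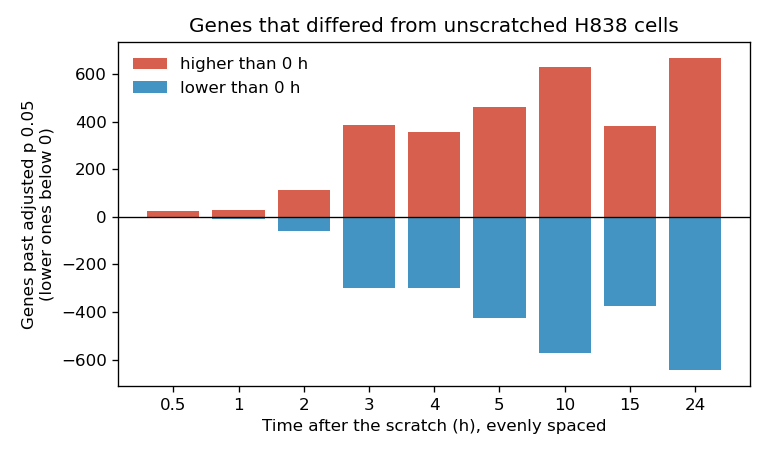
Number of genes past an adjusted p of 0.05 against 0 h (y axis, lower genes drawn below 0) at each time after the scratch (x axis, evenly spaced). Bars are counts from 2 arrays per time, 4 at 24 h. Higher genes numbered 27 at 0.5 h, 630 at 10 h, 384 at 15 h and 669 at 24 h.

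In the early window the immediate early genes rose together. FOS was at least 7.08-fold higher, being above background on 0 of the 4 unscratched arrays. FOSB rose by 2.75 ± 0.17 (6.75-fold), EGR1 by 2.16 ± 0.09, KLF10, a TGF-beta inducible factor, by 0.76 ± 0.12, and DUSP1, a MAP kinase phosphatase, by 0.61 ± 0.09. Of 29 measured immediate early genes 10 were higher and 0 lower (17 higher adjusted over the list alone). The median was 0.32 (adjusted p = 7.37e-31, and 6.97e-05 as an adjusted p with an estimated correlation). The p53 list had 2 higher and 0 lower of 16 (8 over the list alone), the nuclease AEN (0.71 ± 0.11) and the growth arrest gene GADD45A (0.55 ± 0.09), with a median over the list of 0.24 (adjusted p = 2.34e-11, and 6.97e-05 as an adjusted p with an estimated correlation). TGF-beta targets had 3 higher and 0 lower of 14 (7 over the list alone), among them the transcriptional regulators ID2 (0.47 ± 0.08) and BHLHE40 (0.62 ± 0.10), with a median of 0.13 (adjusted p = 2.75e-05, and 0.00245 as an adjusted p with an estimated correlation).

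Some spliceosomal RNAs were also higher early, a group formed after the results were seen and not tested as a list. The U1 RNA genes RNVU1-7, RNU1-3, RNVU1-18 and RNU1-1 rose by 2.85 ± 0.12, 2.83 ± 0.10, 2.73 ± 0.10 and 2.59 ± 0.15. RNU4-2, which encodes U4 RNA, rose by 1.88 ± 0.17 and RNU11 of the minor spliceosome by 1.26 ± 0.18, each detected on 2 of the 4 unscratched arrays. RNU4-1, above background on 0 of these 4, was at least 1.55-fold higher. RNU6ATAC of the minor spliceosome passed as well (0.90 ± 0.12), while other spliceosomal RNAs did not, RNU6-1 at 0.335 ± 0.083 (adjusted p = 0.114) and RNU4ATAC at 0.30 ± 0.14 (adjusted p = 0.425). U1, U4 and SNORD3 copies are nearly identical in sequence, so their probes may not tell the copies apart. Lower early were TXNIP, a glucose-responsive inhibitor of thioredoxin (-0.74 ± 0.09), the complement inhibitor SERPING1 (-0.52 ± 0.11, detected on 4 of 6 early arrays) and WDR25 (-0.50 ± 0.07). The pore-forming protein gene GSDMB was above background on 0 of 6 early arrays (at least 1.21-fold lower). Limma called 53 genes, 46 higher and 7 lower, and 20 under median scaling (18 and 2). On chip 1 and chip 2 taken alone the medians were 0.19 and 0.43 for immediate early genes, 0.16 and 0.29 for p53 targets and 0.10 and 0.25 for TGF-beta targets. Every other list had an adjusted p of at least 0.0753. Beyond the lists named, single members rose, the ephrin receptor EPHA2 by 0.56 ± 0.12 and the stress phosphatase subunit PPP1R15A by 0.38 ± 0.06.

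**Figure D3:**
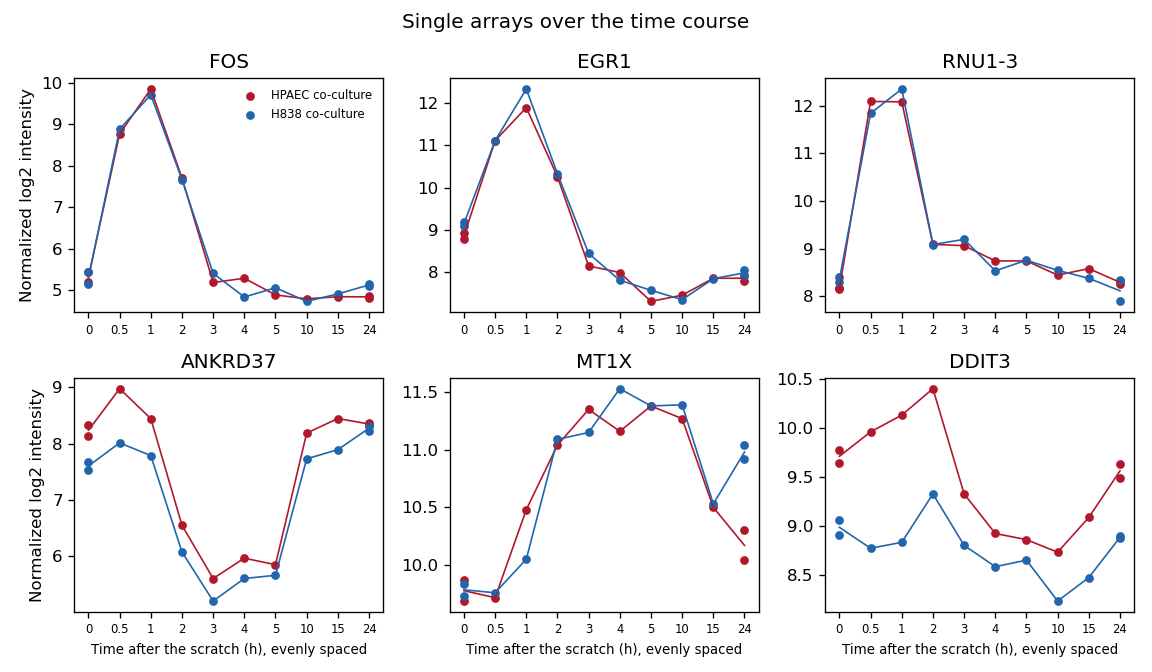
Normalized log2 intensity (y axes) of FOS, EGR1, RNU1-3, ANKRD37, MT1X and DDIT3 on each array over time after the scratch (x axes, evenly spaced); points are single arrays, lines join the means of each co-culture. FOS peaked at 1 h at 9.85 beside HPAEC and 9.71 beside H838 and was not above background at 3 h, while DDIT3 lay higher beside HPAEC at all 10 times.

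At 3 to 5 h genes of the hypoxia response were low. ANKRD37 fell by 2.27 ± 0.11, a change measured with detection on 1 of 6 arrays. PFKFB4 fell by 1.32 ± 0.09, the histone demethylase KDM3A by 1.14 ± 0.07, the glucose transporter SLC2A1 by 1.10 ± 0.11 and the angiogenic factor VEGFA by 0.52 ± 0.08. Of the list 12 of 26 were lower and 0 higher (14 lower adjusted over the list alone). The median was -0.25 (adjusted p = 2.77e-11, and 0.0101 as an adjusted p with an estimated correlation). Mitotic genes fell too: 17 of 33 on the G2/M list were lower and 0 higher (19 over the list alone; median -0.25, adjusted p = 8.3e-11, and 0.0242 as an adjusted p with an estimated correlation). Among them were the phosphatase CDC25C (-0.49 ± 0.10) and the kinase PLK1 (-0.47 ± 0.12).

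Targets of p53 were higher in the same window. The cell cycle inhibitor CDKN1A rose by 0.78 ± 0.07, AEN by 0.80 ± 0.11, the apoptosis effector BAX by 0.55 ± 0.13 and the p53 ubiquitin ligase MDM2, detected on 2 of 4 unscratched arrays, by 0.42 ± 0.11. On the list 10 of 16 were higher and 0 lower (12 over the list alone; median 0.29, adjusted p = 2.22e-08, and 0.000736 as an adjusted p with an estimated correlation). TGF-beta targets had 6 of 14 higher and 0 lower (6 and 1 over the list alone; median 0.19, adjusted p = 0.000615, and 0.0101 as an adjusted p with an estimated correlation). The largest were the inhibitors of differentiation ID2 (1.00 ± 0.08), ID1 (0.72 ± 0.07) and ID3 (0.70 ± 0.08). The metallothionein MT1X, whose close paralogs its probe may also read, rose by 1.54 ± 0.15. The zinc exporter SLC30A1 rose by 1.16 ± 0.09, the methionine adenosyltransferase MAT2A by 1.30 ± 0.09 and LINC00472, a long non-coding RNA, by 1.51 ± 0.16. RAB7B, a late endosomal GTPase, was at least 2.66-fold higher than on the unscratched arrays, where it was not above background.

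Among 29 immediate early genes 8 were higher, with FOSB at 1.25 ± 0.17, and 2 lower, with EGR1 at -1.12 ± 0.09 (9 and 2 over the list alone; median 0.14, adjusted p = 0.0247). That call was lost otherwise (adjusted p = 0.316 with an estimated correlation). A pair of further calls were lost in that way. The ER stress list had 1 higher, ATF5, a transcription factor, and 4 lower, with DDIT3 at -0.49 ± 0.13 (1 and 5 over the list alone; median -0.090, adjusted p = 0.0402, and adjusted p = 0.316 with an estimated correlation). The NRF2 and redox list had 4 of 18 higher, the antioxidant enzyme genes SRXN1 and HMOX1 and the metallothioneins MT1E and MT1X (4 over the list alone; median 0.079, adjusted p = 0.0402, and adjusted p = 0.538 with an estimated correlation). In other lists, which had an adjusted p of at least 0.35, TNFRSF1A rose by 0.25 ± 0.08, the endothelial list gene SOX18 by 0.27 ± 0.09, and the leukocyte list gene CD68, a lysosomal protein, fell by 0.28 ± 0.07. Limma called 1756 genes in this window, 919 higher and 837 lower (52.3% higher), against 585 under median scaling, of which 35.2% were higher. On chip 1 and chip 2 taken alone the medians were -0.29 and -0.15 for hypoxia, -0.23 and -0.25 for G2/M, 0.32 and 0.29 for p53 targets and 0.14 and 0.27 for TGF-beta targets.

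From 10 to 24 h mitotic genes were below the unscratched level. CDC25C fell by 0.69 ± 0.10, PLK1 by 0.64 ± 0.12, the kinesin KIF20A by 0.57 ± 0.07 and the ubiquitin-conjugating enzyme UBE2C by 0.52 ± 0.07. Of 33 genes 26 were lower and 0 higher (28 over the list alone; median -0.36, adjusted p = 1.3e-20, and 0.00788 as an adjusted p with an estimated correlation). Cholesterol synthesis had 8 of 21 lower and 0 higher (8 over the list alone), with the sterol sensor INSIG1 at -0.73 ± 0.06 and the synthase HMGCS1 at -0.41 ± 0.08 (median -0.21, adjusted p = 8.43e-06, and 0.0236 as an adjusted p with an estimated correlation). The ER stress and amino acid list had 11 of 25 lower and 0 higher (15 and 1 over the list alone), with AARS1 at -0.58 ± 0.11, DDIT3 at -0.53 ± 0.13 and ATF4, the master regulator of the response, at -0.42 ± 0.07 (median -0.20, adjusted p = 2.2e-07, and 0.0141 as an adjusted p with an estimated correlation).

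The hypoxia list had 10 of 26 lower, with PFKFB4 at -0.89 ± 0.09, and 1 higher, the mTOR inhibitor DDIT4 at 0.80 ± 0.13 (12 and 2 over the list alone; median -0.17, adjusted p = 8.43e-06, but adjusted p = 0.0827 with an estimated correlation). Heat shock genes had 6 of 16 higher and 0 lower (6 and 1 over the list alone), among them the co-chaperones HSPH1 (0.42 ± 0.06) and DNAJB1 (0.40 ± 0.06) and the near-identical HSPA1A and HSPA1B, whose probes may not tell them apart (0.62 ± 0.08 and 0.63 ± 0.08). Its median of 0.090 passed at the preset correlation (adjusted p = 0.004, but adjusted p = 0.0857 with an estimated correlation). Of the migration list, the collagenase gene MMP1 fell by 0.80 ± 0.12 and the gelatinase gene MMP9 by 0.85 ± 0.13, while ITGAV rose by 0.30 ± 0.07. The migration list as a whole had 4 lower and 1 higher of 16 (6 and 2 over the list alone; median -0.10, adjusted p = 0.0748, and adjusted p = 0.111 with an estimated correlation).

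Outside the lists TMEM119 rose by 1.27 ± 0.12 and CRYBA1 by 1.12 ± 0.09, the circadian output factors TEF (detected on 5 of 8 late arrays) and DBP fell by 1.09 ± 0.10 and 0.96 ± 0.10, and VGF fell by 0.91 ± 0.06. Among single markers of other cell types, the matrix genes POSTN, LUM and COL3A1 of the fibroblast list rose by 0.53 ± 0.10, 0.38 ± 0.12 and 0.33 ± 0.09, and the smooth muscle genes TAGLN and CNN1 and the receptor PDGFRB fell by 0.48 ± 0.12, 0.38 ± 0.07 and 0.39 ± 0.11. The leukocyte list gene CD68 fell by 0.69 ± 0.07, and the endothelial list gene MMRN1 rose by 0.27 ± 0.09. None of these 3 lists passed (adjusted p = 0.885, 0.361 and 0.773). Limma called 1780 genes late, 911 higher and 869 lower (51.2% higher), against 571 under median scaling, of which 72.9% were higher. On chip 1 and chip 2 taken alone the medians were -0.26 and -0.42 for G2/M, -0.15 on both for cholesterol synthesis and -0.34 and -0.24 for ER stress. Of the 140 list tests 21 passed at the preset correlation and 12 with an estimated one: ER stress and NF-kB targets for the co-culture, immediate early, p53 and TGF-beta targets early, hypoxia, G2/M, p53 and TGF-beta targets in the middle, and G2/M, ER stress and cholesterol synthesis late. Each of these 12 kept the sign of its median under every scaling tried, but some sizes moved. Median scaling brought immediate early genes from 0.32 to 0.21 and TGF-beta targets from 0.13 to 0.070 early, and cholesterol synthesis from -0.21 to -0.12 late. The early median of p53 targets went from 0.24 to 0.14 with the series matrix values, and that of TGF-beta targets in the middle window from 0.19 to 0.11 without background correction. When times were redrawn among the arrays of each co-culture, TGF-beta targets gave a median as large in 17 of 100 splits early and in 5 of 100 in the middle window. Each of the other calls was matched in at most 4 of 100 splits of its kind. For the co-culture this gives little support, since leukocyte and fibroblast markers, which did not pass, also reached only 1 of 100. Redrawn co-culture labels follow the chip less closely than the real ones, so their medians are not on an equal footing.

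**Figure D4:**
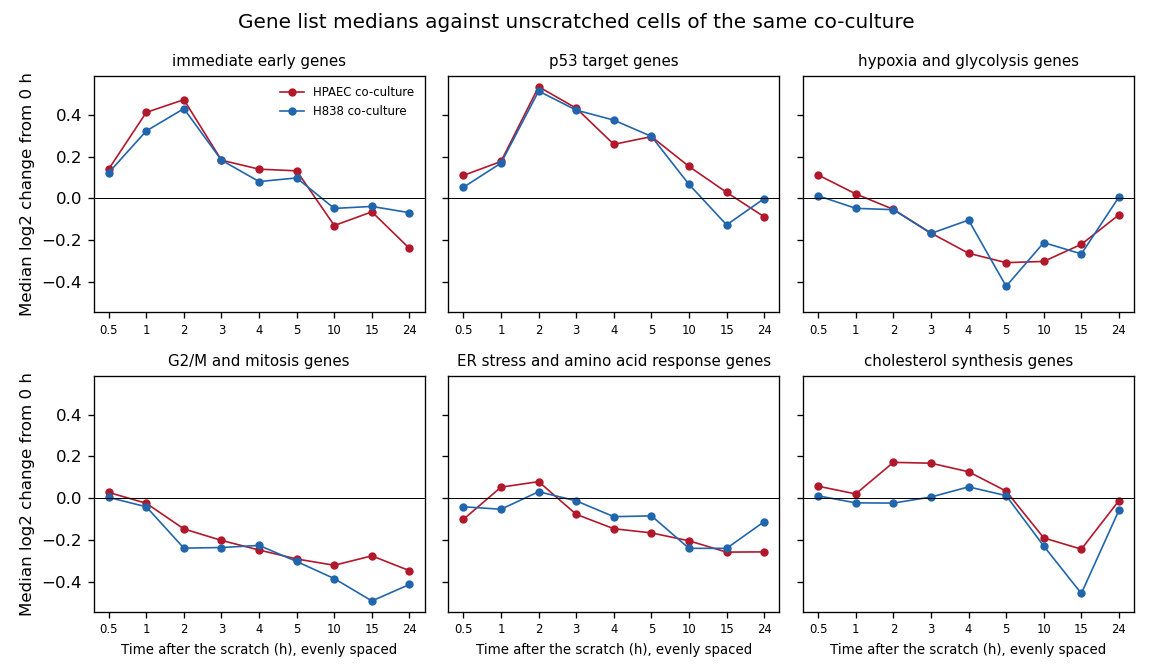
Median log2 change from the unscratched cells of the same co-culture (y axes) over the genes of 6 lists after the scratch (x axes, evenly spaced). Lines join medians of single arrays, or of duplicate means at 24 h. The p53 list peaked at 2 h (0.54 beside HPAEC, 0.51 beside H838).

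Whether the changes after the scratch depended on the neighbouring cells was tested by the co-culture by time interaction. Limma called 0 genes (530 at an unadjusted p under 0.05), and 0 on the duplicated arrays alone (1406). The smallest p-values belonged to the scaffold protein gene DLG1, the zinc finger gene ZNF138 and LSM14B, an RNA-binding protein gene, at adjusted p of 0.548 to 0.722. Among the lists, cholesterol synthesis had a positive interaction in the middle window (median 0.22, adjusted p = 0.0454, but adjusted p = 0.827 with an estimated correlation) and in the late window (median 0.12, adjusted p = 0.0228, but adjusted p = 0.948 with an estimated correlation). The late interaction of NRF2 and redox genes was negative (median -0.16, adjusted p = 0.00142, but adjusted p = 0.115 with an estimated correlation). In simulated data 18 of 100 differences of 0.5 and 72 of 100 of 1 on the log2 scale were recovered. Many differences of such sizes would thus be missed with this number of arrays. Real recovery may be lower. The model used 1 mean per co-culture and window, so changes between times of a window enter its residual spread. The simulated genes had no such changes. The estimated correlation of cholesterol synthesis genes was 0.259 here and 0.0555 for the co-culture effect. That of NRF2 and redox genes was 0.0463 here and 0.208 for the co-culture effect. Whether changes within a window raised the value for cholesterol synthesis was not tested.

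At the duplicated ends of the time course TMEM119 rose from 6.04 ± 0.11 (mean log2 intensity ± SD, n = 2) to 7.94 ± 0.10 beside HPAEC and from 6.59 ± 0.33 to 8.51 ± 0.0088 beside H838. Beside HPAEC 580 genes differed between 24 and 0 h, 331 higher and 249 lower, among them CRYBA1 at 1.73 ± 0.09 and the kinetochore gene CENPQ at 1.32 ± 0.17. ABAT, a GABA-degrading enzyme, was at least 1.31-fold higher, VGF fell by 1.45 ± 0.09 and MMP1 by 1.06 ± 0.11. Beside H838 27 genes differed, 10 higher and 17 lower. HMOX1, which encodes heme oxygenase, rose by 1.74 ± 0.12, MT1X by 1.19 ± 0.14 and DDIT4 by 1.14 ± 0.10. MMP1 fell by 1.31 ± 0.12, MMP9, detected on 1 of 2 arrays at 24 h, by 1.24 ± 0.13, and DHRS2, a mitochondrial reductase, was at least 2.33-fold lower. The difference in these changes passed for 0 genes (smallest adjusted p = 0.113), so the unequal counts do not show unequal responses. Under median scaling 83.6% of calls beside HPAEC were higher, against 57.1%, and 21.3% of those beside H838, against 37%. Both counts rest on pairs of arrays: leaving out 1 of the 8 arrays left 0 to 74 calls beside HPAEC and 0 beside H838.

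Between the co-cultures limma called 0 genes at 0 h (2389 at an unadjusted p under 0.05) and 0 at 24 h (1158). At 0 h the count was 159 under median scaling, 534 without background correction, 558 with the series matrix values and 592 with detection required on all 24 arrays. The smallest p-values at 0 h belonged to SNORA79, a small nucleolar RNA, RAD51B and the chromatin gene ARID4B, the last at -1.16 ± 0.10 (smallest adjusted p = 0.0609). SNORA79 and RAD51B were above background on 0 of 2 HPAEC arrays at 0 h, so no log2 difference is given. At 24 h they belonged to HMOX1 at -1.34 ± 0.12 (adjusted p = 0.192), the giant scaffold gene AHNAK at -0.64 ± 0.09 and the repair gene ERCC6, which was above background on 0 HPAEC arrays and 1 H838 array. Simulated differences of 0.5 were recovered for 0 of 100 genes at either time.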

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

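The tests of small nuclear RNA, of the stress list and of the hypoxia list, and the regroupings counted with an estimated correlation, were chosen only after the results were seen; the other regroupings were planned.

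The co-culture by time interaction set some lists apart in camera at its preset correlation, and each of these calls was lost with an estimated correlation (adjusted p = 0.827, 0.948 and 0.115 in the order given here). The median interaction of cholesterol synthesis genes was 0.216 in the middle window and 0.119 in the late window, and that of NRF2 and redox genes was -0.163 in the late window, on the log2 scale. Probes without a single gene name, which no gene test used, also carried signal: 423 of 4762 passed the threshold of the time effect (8.88%, against 16.6% of named probes) and 14 passed that of the co-culture effect.

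The early rise of U1, U4, U11 and U3 RNA covered 10 genes, with changes up to 2.85 and a median of 1.69 when RNU4-1, undetected on the unscratched arrays, is set to its bound of 0.631. If all small RNA were kept in equally larger amounts in the early preparations, other small nucleolar and Cajal body RNAs would rise alike. The 75th percentile of their early change was 0.254 over all 92 tested and 0.234 over the 34 detected on every unscratched array. This argues against such an equal gain as the whole cause, although 7 of the 92 had changes above that bound (SCARNA9 1.29 and SNORD13 1.05 passing, SNORA79 1.17, SCARNA8 0.78, SCARNA16 0.71, SCARNA14 0.69 and SCARNA13 0.64 not). The group was picked for its rise, so part of this gap is built in, and an unequal gain was not tested. Of further small RNAs RN7SK (0.61), RNU6ATAC (0.90), RNY1 (0.415) and RNY4 (0.498) rose past the threshold. Others, such as RNY5 (0.521), RNY3 (0.033) and RN7SL1 (-0.032), did not pass. A chip difference is argued against by the smallest change at 1 h between arrays of the same chip and co-culture, 1.6, while handling of the plates apart from the scratch cannot be told apart from the wound, because 0 unscratched arrays were taken after 0 h. A burst of these transcripts after wounding may therefore explain the rise, but a change in how they were primed or processed was not tested.

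Next to HPAEC the ER stress and amino acid list was higher by a median of 0.213. A chip difference would vanish between arrays of the same time and chip, yet the lowest of those 4 medians was 0.174. Chip was already a term of the model, and these pairs carry much of its estimate (correlation 0.917 across genes). The list was also picked for that estimate, so the pairs are not a separate test of it. Endothelial RNA in the lysates would bring endothelial markers, and the median over their 39 probes was -0.00235 (quartiles -0.0774 and 0.0404), with VWF, CDH5 and KDR detected on 0 arrays. Per the labels both co-cultures were kept in the endothelial medium, so its recipe does not differ between them. A response of the tumour cells may therefore explain the difference, to factors released or nutrients used up by HPAEC or by the added H838 cells. No array held H838 cells without a neighbour, so a rise beside HPAEC cannot be told apart from a fall beside H838. No test here separates these. The difference also ran against the change over time, since the list's late median was -0.204. The hypoxia list did so too (0.142 and -0.166), while the NF-kB and TNF list did not (0.191 and 0.00933). On the leading principal component the 0 h arrays lay at 18.62 and 11.4 beside HPAEC and at 2.505 and -0.9227 beside H838. At 24 h these were -5.267 and -7.048, and -14.13 and -13.71. Whether the co-cultures differed in a state that also changes with time was not tested.

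The fall of hypoxia genes at 3 to 5 h was seen on each chip, the higher of these medians being -0.146, and under each scaling, the highest median being -0.221. Both argue against chip and scaling as the whole cause. Handling cannot be told apart here either, since 0 unscratched arrays were taken after 0 h. Fresh air or medium at scratching could lower these genes as well as the wound itself.

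Regroupings tested whether chance could give the counts, with 100 splits each. For genes the real counts stood above those of all other splits. The real co-culture count was 232 and the highest other 1, with labels redrawn within each time. With times redrawn within each co-culture, the real and the highest other counts were 2629 and 47 for the time effect, 53 and 1 early, 1756 and 10 in the middle and 1780 and 2 late. In each of these cases 1 split, the real one, gave as many. Redrawn labels leave the real differences in the residual spread, which lowers the other counts, so these splits do not by themselves exclude chance. For the lists at the preset correlation chance cannot be excluded: the co-culture gave 3 lists and the highest other split 4 (19 splits as many), and the windows gave 15 and the highest other split 23 (22 splits as many). With an estimated correlation the co-culture gave 2 lists and the highest other split 3 (2 splits as many), so chance is not excluded. The windows gave 10 and the highest other split 2 (1 split as many), with the same limit as the gene counts. For single lists among these calls, TGF-beta targets gave a median as large in 17 of 100 splits early and 5 in the middle window, so chance cannot be excluded for these calls. Splits of the co-culture do not decide for its 2 lists, because lists that did not pass were matched as rarely.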

How the results depend on the processing

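The fits of each chip alone with windows in place of times, and the co-culture effects from the window model, were chosen after seeing the data; the other alternatives were planned. Signal over background limits these data: no more than 37.13% of probes were detected on any array. Of the values of named genes under the alternatives 12114 of 13591 kept direction and side of the threshold. Fits with 1 array left out made up 8775 of these 12114. A further 1155 fell below it and 255 passed it. Another 67, not past it in the main fit, changed sign, and 0 past it did. Some settings lost a larger share. With windows, chip 1 alone kept 105 while 149 fell below, and chip 2 alone kept 98 while 150 fell. Median scaling kept 324 while 81 fell, and pairs of the same time and chip kept 61 while 34 fell. Without background correction 377 were kept and 3 fell. Of 280 list values 254 stayed, 11 fell below the threshold and 2 passed it. Another 13, not past it in the main fit, changed direction, and 0 past it did. The co-culture by time interaction called 0 genes under every setting run, including a spline of time. Except where stated, the cause was not tested.

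Counts that moved by more than 1.5 times are given by setting. Without background correction the co-culture effect called 393 genes, 0 h 534, 24 h 6, 24 against 0 h 1717 beside HPAEC and 522 beside H838. Median scaling gave 5 for the co-culture, 1347 for time, 20 early, 585 middle, 571 late, 159 at 0 h, 5 at 24 h and 155 for 24 against 0 h beside H838. The series matrix gave 366 for the co-culture, 558 at 0 h, 18 at 24 h, and 1596 and 581 for 24 against 0 h. Without a detection filter the co-culture called 129, and 24 against 0 h called 62 and 0. With detection on all arrays the co-culture called 423, 0 h 592, 24 h 1, and 24 against 0 h 1780 and 534. Single probes gave 137 for the co-culture, and 242 and 3 for 24 against 0 h. Without chip the co-culture called 1723, 0 h 8, 24 h 1, and 24 against 0 h beside H838 194. With chip as a random block these were 1949, 8, 1 and 196. The chip term raised the median SE of the co-culture effect from 0.0582 to 0.0823, and 213 of the 232 genes were also called without it. Pairs of the same time and chip, chip 1 alone and chip 2 alone each gave 0 for the co-culture from fewer arrays, scratched arrays only gave 2, and the window model gave 58 (and 2 at 0 h). With windows, chip 1 alone gave 1 early, 0 middle and 4 late, and chip 2 alone 0, 0 and 0. List tests passed 12 times with an estimated correlation, against 21.

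A replicate block in place of chip gave 1664 for the co-culture, 2 at 0 h, and 381 and 62 for 24 against 0 h. The replicate numbers do not pair samples, since differences between replicates correlated across genes at -0.0462 to 0.133 between groups.

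Leaving out 1 array at a time, the co-culture count ranged from 10 to 261, time from 2057 to 2689, early from 31 to 69, middle from 970 to 1831, late from 856 to 1864, the interaction, 0 h and 24 h from 0 to 0, and 24 against 0 h from 0 to 74 beside HPAEC and from 0 to 0 beside H838. The co-culture count was 10 without the H838 0 h replicate 1 array and 129 without replicate 2, 18 without the HPAEC 0 h replicate 2 array, 50 without either 0.5 h array, 136 without either 5 h array, and 144 and 143 without the HPAEC 24 h replicates 1 and 2. Early was 31 without the H838 0 h replicate 1 array. Without that array middle was 1067, and without the HPAEC 0 h replicates 1 and 2 it was 1155 and 970, with late at 1069 and 856. Late was 1153 without the HPAEC 10 h array. For 24 against 0 h beside HPAEC, leaving out an HPAEC 0 h or 24 h array left 0 genes, an H838 0 h array 74 and an H838 24 h array 3. Beside H838 each of the 8 left 0. A lone array was taken to vary like the other groups.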

Other observations

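The tests of the clock, metallothionein and SR family lists were chosen only after genes of each had been seen to change, and their permutation tests after the fry values had been seen; the other values come from the planned models.

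Single splicing factor genes of the SR family changed after the scratch. At 3 to 5 h SRSF6 was higher by 1.09 ± 0.06 (log2 ± SE), SRSF5 by 0.75 ± 0.07, SRSF7 by 0.71 ± 0.09 and SRSF3 by 0.63 ± 0.09, while SRSF4 was lower by a change of -0.22 ± 0.06. At 10 to 24 h SRSF7 (0.82 ± 0.09), SRSF6 (0.62 ± 0.06), SRSF3 (0.60 ± 0.09) and SRSF2 (0.49 ± 0.06) stood above the unscratched level. Some Cajal body RNAs, which guide modification of spliceosomal RNA, were above background on 0 of 6 arrays in the middle window, which makes SCARNA20 at least 1.48-fold and SCARNA8 at least 1.11-fold lower.

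Single genes of the entry into S phase differed in direction at 3 to 5 h. The cyclin genes CCNE1 and CCND1 rose by 0.53 ± 0.06 and 0.40 ± 0.06, and the licensing factor CDT1, the helicase factor CDC45 and the polymerase subunit POLA2 fell by 0.56 ± 0.08, 0.39 ± 0.06 and 0.34 ± 0.06. Of 30 genes of the G1/S list 5 were higher and 7 lower (5 and 9 adjusted over the list alone; adjusted p = 0.35). Of 17 interferon-stimulated genes 3 were lower in that window, the signalling factor IRF9 (-0.46 ± 0.07), the exonuclease ISG20 (-0.35 ± 0.09) and the ubiquitin-like ISG15 (-0.26 ± 0.07), with an adjusted p of 0.35 for the list. In the epithelial list the tight junction scaffold TJP1 rose by 0.35 ± 0.07 and the desmosomal cadherin DSG2 fell by 0.25 ± 0.07.

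DBP and TEF are outputs of the circadian clock, and their fall led to the hypothesis that the clock genes as a set had moved one way by 10 to 24 h. Without these genes the permutation test of the median over 8 genes gave p = 0.785 and limma's fry p = 0.358 for a common direction, so a shared fall was not shown. PER2 (-0.69 ± 0.09) and PER3 (-0.52 ± 0.10) were lower and CLOCK (0.26 ± 0.08) higher, and BMAL1, above background on 0 of 4 unscratched arrays, was at least 1.18-fold higher. A reset or shifted phase could give opposite changes of this kind, but no test of phase was run.

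MT1X and SLC30A1 respond to metal, which led to the hypothesis that metallothioneins rose together at 3 to 5 h. Without MT1X and SLC30A1, fry gave p = 0.00687 for a rise over 6 genes, but the permutation test of their median (0.243) gave p = 0.149. The camera p was 0.128 with an estimated correlation. Single genes passed, MT1E (0.81 ± 0.15), MT1F (0.42 ± 0.08) and MT1H (0.38 ± 0.11), and their probes may read one another. A release of zinc could raise these genes, but a rise of the set beyond chance was not shown.

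SRSF6 and SRSF7 led to the hypothesis that SR family genes rose together at 3 to 5 h. Without SRSF6 and SRSF7, fry gave p = 6.84e-06 for a rise over 11 genes, 4 higher and 1 lower, but the permutation test of their median (0.196) gave p = 0.0900. Camera gave p = 0.0196 with an estimated correlation. In the late window, which the hypothesis did not name, 3 of these 11 were higher and 0 lower (median 0.231), with a permutation test p = 0.0410, fry p = 2.02e-06 and camera p = 0.00650 with an estimated correlation. Redrawn times leave the changes of other windows in the comparison, which makes the permutation test strict. A rise of the set remains open at 3 to 5 h and is only marginal later, and it was found and tested on the same arrays.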
